A study of Arabidopsis thaliana and Cucumis sativus and Glycine max with 60 samples.

How the data were processed

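The series measured mRNA by RNA sequencing in zones cut along the growing tip of seedling primary roots in 7 vascular plants. The plants were Arabidopsis (cultivar Columbia), cucumber, soybean, rice, tomato, maize and the lycophyte Selaginella moellendorffii. Roots of 6 species were cut into a meristematic zone (MZ), an elongation zone (EZ) and a differentiation zone (DZ). Selaginella was cut into an MZ and a joint elongation and differentiation zone (EDZ). Every zone of every species had 3 libraries, which the design text calls biological replicates, for 60 samples in all. Plants were 4 days from plating, except tomato at 6 days and Selaginella, grown from bulbils, at 21 days. Per the labels' protocols, plants grew on agarose medium in constant light, RNA was taken with a column kit and libraries were made with an Illumina TruSeq kit. Whether the kit kept strand is not given in the sources used here.

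Per the submitters' processing notes, FastQC and TopHat2 were run. Their versions, the counting tool, the gene lengths and the filters are not given in the sources used here. Per the labels, reads were mapped with annotations of Ensembl release 19 for Arabidopsis, soybean, rice, tomato and maize and of Phytozome for cucumber and Selaginella. The authors deposited RPKM values (reads scaled to gene length and to the number of mapped reads, the unit named by the files) in 2 tables of gene rows. The tables hold MZ, EZ and DZ columns of 6 species in 1 case and MZ and EDZ columns of 7 species in the other. Each column stacks the libraries of that zone and number, species after species, and rows were assigned to a species by their locus names. The MZ values of the 6 shared species were identical in both tables. The EDZ values of those 6 species lay between the same-numbered EZ and DZ values in 96.6% to 99.7% of the genes compared, with a median DZ weight of 0.434 to 0.549. This median was within 0.014 of the share of DZ in the summed depth. These columns were therefore read as pools of the EZ and DZ libraries, with no further samples, although the labels do not say so. The EDZ comparison of those species therefore reuses the libraries of the other comparisons, and only in Selaginella does it rest on libraries of its own. The 13665 rows whose IDs name no species were left out.

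The files hold no read counts. Relative depth was estimated from the low values, where 1 read has an RPKM that is inverse to depth. Relative to MZ replicate 1 of the species it was 0.917 to 3.33 in Arabidopsis, 0.99 to 1.35 in cucumber, 1 to 1.33 in soybean, 1 to 4.01 in rice, 0.936 to 1.14 in tomato, 0.923 to 1.08 in maize and 0.584 to 1.07 in Selaginella. In Arabidopsis, with gene lengths of the reference annotation, this corresponded to about 7 to 7.67 M reads in the 3 libraries numbered 1 and 19.3 to 24.8 M reads in the other 6. At those depths 1 read on a gene of 1 kilobase is worth 0.13 to 0.143 RPKM and 0.0403 to 0.0519 RPKM, and lower values were not resolved. An RPKM of 0 is given as listed at 0, since it can also be a failed estimate.

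Tests used limma 3.58.1 in R 4.3.3 on log2(RPKM + 1), so fold changes of low genes are understated. Quantile normalization moved the median change of all genes by over 0.1 log2 units in some comparisons. It moved by -0.19 in Arabidopsis EDZ against MZ, by -0.11, -0.14 and -0.22 in cucumber EZ against MZ, DZ against EZ and EDZ against MZ, by -0.13 in soybean and -0.12 in rice EDZ against MZ, by -0.16 and -0.22 in tomato DZ against EZ and EDZ against MZ, and by 0.10 in Selaginella. Directions are given on the reported scale. Each species was fitted alone, with its 9 libraries in 1 fit for EZ against MZ and DZ against EZ, and with its 6 columns for EDZ against MZ. Genes with at least 1 RPKM in at least 3 libraries were tested. The fit used lmFit and eBayes with a mean trend and robust estimation, two-sided moderated tests and Benjamini-Hochberg adjustment over all genes tested in that species and comparison. A gene was called at an adjusted p under 0.05 and a change of at least 2-fold. All adjusted p-values below come from limma, and errors of log2 changes are its standard errors. Tables were handled with Python 3.11.15, pandas 2.3.3 and NumPy 2.4.6, and plots were drawn with matplotlib 3.10.9.

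In Arabidopsis, 22 gene lists fixed before the data were examined were tested with camera in limma, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists of a comparison. They cover mitosis and cytokinesis, DNA replication, core histones, meristem regulators, root cap regulators, nucleolar proteins, expansins, xyloglucan endotransglucosylase/hydrolases (XTH), cellulose synthesis of the primary wall, vacuolar proton pumps, aquaporins, xylem and secondary wall, monolignol synthesis, endodermis and suberin, root hair growth, epidermal patterning, nutrient transport, auxin, cytokinin, phloem, photosynthesis, and wounding and touch. EXPA7 and EXPA18 stand in both the expansin and the root hair list. The same test with a correlation estimated for each list called 0 of 22 lists in each comparison, with adjusted p of 0.389 or more, and its adjusted p stands beside each call. Libraries of the same number deviated together, with a correlation of deviations from the zone means over 0.1 for every number, in 15 of the 19 comparisons. Among these, not every library correlated best with its own number in DZ against EZ of Arabidopsis and of rice. The pairing comes from the values, since the titles give only the numbers. In Arabidopsis, tomato and Selaginella the description numbers of the labels also follow each other within a replicate number. Paired fits are given as an alternative.

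The tests were tried on simulated data with the means and spread of real genes, 200 of them changed. The changed genes were drawn only from those above a floor of expression, so changes in the lowest genes were not tried. Noise was independent between libraries, whereas same-numbered soybean libraries deviated together in DZ against EZ (r = 0.311 to 0.805). The real Arabidopsis EZ against MZ and DZ against EZ called 38.7% and 36% of genes, a far larger share. The shares recovered below are therefore not the power of the real tests. For Arabidopsis EZ against MZ on 19049 genes, 60 of 100 changes of 1.5 log2 units and 84 of 100 changes of 3 units were recovered with 3 false calls. For Arabidopsis DZ against EZ on 19057 genes these were 60 and 94 of 100 with 8 false calls, for soybean DZ against EZ on 32090 genes 48 and 83 of 100 with 10 false calls, and for Selaginella EDZ against MZ on 12217 genes 77 and 98 of 100 with 5 false calls. The list test, on 19640 simulated genes of Arabidopsis EZ against MZ, called the 1 raised list and 0 of 20 unchanged lists in limma. The simulated genes took means and spread from real genes but not their correlation within a list. In the real lists of that comparison the median estimated correlation was 0.482, above the preset one. The simulation therefore cannot show how many false list calls such correlation would cause.

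Gene names of Arabidopsis come from a reference gene table of the TAIR10.1 assembly, in which 32809 of 33550 gene rows were found; since the labels name TAIR10, its coordinates are not given. Named genes follow a rule set before the data were examined. In each Arabidopsis comparison it takes the 5 largest called rises and falls with at least 10 RPKM in the higher zone, and in each list up to 2 called rises and 2 called falls with at least 5 RPKM. In the other species, whose IDs have no names here, it takes the 2 largest called rises and falls per comparison with at least 10 RPKM, of which at most 2 IDs per direction are given for a species. The IDs given are not always the largest. The largest falls of EZ against MZ in cucumber, soybean, tomato and maize, listed at 0 in the EZ, are not given. A named gene of the auxin list is not reported here. Genes with near-identical copies, such as histones, aquaporins and light-harvesting proteins, and genes that overlap another gene are uncertain, since the counting could split or share their reads. Among named genes, 14 of 55 in EZ against MZ, 18 of 56 in DZ against EZ and 13 of 58 in EDZ against MZ overlap another gene.

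Alternatives were a pseudocount of 0.1, no filter on low values, quantile normalization, no fold minimum, blocks on the replicate number or on runs of the description numbers, each library left out in turn and, added after seeing the data, sets of same-numbered libraries left out together. For the Arabidopsis gene lists the alternatives were the estimated correlation, the replicate block, the pseudocount and quantile normalization. The list tests were not run with a library left out. Gene lists in the other species, families shared by all species and correlations between species need family identifiers and were not analysed here.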

Results

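The data hold the expression of genes along the root in 60 libraries, 3 for each zone of each species. The number of genes tested was 19640 in Arabidopsis, 16693 in cucumber, 33244 in soybean, 20061 in rice, 19892 in tomato and 25756 in maize over the 9 libraries of a species, and 12650 over the 6 libraries of Selaginella. Between 20778 and 23157 Arabidopsis genes were above 0 in a library. Across genes, log2 values of libraries of the same zone correlated at 0.891 to 0.978 in Arabidopsis, 0.966 to 0.983 in cucumber, 0.83 to 0.974 in soybean, 0.797 to 0.985 in rice, 0.94 to 0.982 in tomato, 0.919 to 0.957 in maize and 0.944 to 0.976 in Selaginella. Libraries of different zones correlated at up to 0.884 in Arabidopsis, 0.914 in cucumber, 0.969 in soybean and 0.933 in rice. In tomato, maize and Selaginella the highest such values were 0.861, 0.856 and 0.795. In soybean and rice the highest value between zones was thus above the lowest within a zone. Genes are not independent replicates. Following the design of the series, the comparisons ask how gene expression changes as cells of the root pass from division to elongation and then to differentiation.

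Between the MZ and the EZ of Arabidopsis, 6 of 22 gene lists were called lower, among them mitosis (24 of 24 genes fell), the root cap (4 of 4) and the nucleolus (5 of 5). Another 11 were called higher, among them aquaporins (18 of 19 genes rose and 1 fell), cellulose synthesis (8 of 8) and root hair growth (20 of 24). With an estimated correlation 0 of these lists were called by camera in limma, with adjusted p = 0.472 or more with an estimated correlation. PLT1 (AT3G20840), a transcription factor that maintains the root stem cell niche, fell from 32.3 ± 12.2 RPKM in MZ to 0.718 ± 0.795 in EZ (SD, n = 3), a log2 change of -4.29 ± 0.70 (adjusted p = 0.0017). EXPA17 (AT4G01630), an expansin, rose from 10.8 ± 11.9 to 302 ± 161 RPKM, a log2 change of 5.03 ± 0.75 (adjusted p = 0.00126). The tonoplast aquaporin TIP2;1 (AT3G16240) rose from 30.8 ± 38.2 to 1183 ± 659 RPKM. In all, 3596 genes rose and 4009 fell of 19640 tested, and which of these was larger turned in 3 of 15 alternatives, such as without MZ replicate 2 (3183 and 3174) or EZ replicate 3 (3120 and 3006). Without MZ replicate 2, genes reaching 1 RPKM only in the MZ were not tested, so that turn decides nothing about this library.

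Every gene of the mitosis and cytokinesis list fell in the EZ, 24 of 24 over all genes and 24 adjusted over the list alone (camera adjusted p = 3.66e-07, adjusted p = 0.502 with an estimated correlation). The mitotic cyclin CYCB2;4 (AT1G76310) went from 33.6 ± 4.9 to 4.52 ± 3.47 RPKM. The cytokinesis syntaxin KNOLLE (SYP111, AT1G08560) went from 115 ± 16.9 to 17.6 ± 11.4 RPKM. Of 18 DNA replication genes 12 fell, also 12 adjusted over the list alone, and 6 did not pass (adjusted p = 0.000636, adjusted p = 0.519 with an estimated correlation). Among them RNR1 (AT2G21790), of nucleotide reduction, fell from 61.3 ± 9.94 to 13 ± 7.62 RPKM. The helicase subunit MCM6 (AT5G44635) went from 23.2 ± 3.44 to 4.26 ± 2.43 RPKM. The list of core histones was lower as a whole, with a median log2 change of -0.59 (adjusted p = 0.0217, adjusted p = 0.572 with an estimated correlation). Of its 22 members only HTB1 (AT1G07790) fell, by 1.42 on the log2 scale. In limma 0 were called adjusted over the list alone, with 6 at an unadjusted p under 0.05. The call of HTB1 was lost without MZ replicate 1 (adjusted p = 0.053), MZ replicate 2 (0.0628), MZ replicate 3 (0.0646) or EZ replicate 3 (0.0701), and without the 3 libraries numbered 3 (0.0622). All 5 nucleolar proteins fell, 5 adjusted over the list alone (adjusted p = 0.0172, adjusted p = 0.519 with an estimated correlation). Nucleolin NUC1 (NUC-L1, AT1G48920) went from 806 ± 97.2 to 109 ± 57.6 RPKM. Fibrillarin FIB2 (AT4G25630) went from 556 ± 56.5 to 71.9 ± 42.7 RPKM.

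Of 11 meristem regulators 6 fell and 5 did not pass, with 7 lower adjusted over the list alone (adjusted p = 0.00729, adjusted p = 0.472 with an estimated correlation). The meristem growth peptide gene RGF1 (AT5G60810) fell by 4.88 on the log2 scale and PLT1, given above, by 4.29, whereas SHR and SCR, which pattern the ground tissue, were not called, with log2 changes of 0.12 and -0.25. All 4 root cap regulators fell, 4 adjusted over the list alone (adjusted p = 0.0114, adjusted p = 0.472 with an estimated correlation), SMB (AT1G79580) from 22.7 ± 10.4 to 0.688 ± 0.921 RPKM. BRN1 (NAC015, AT1G33280) went from 17.3 ± 12.9 to 0.354 ± 0.0925 RPKM. Epidermal patterning did not pass as a list (adjusted p = 0.36). Of its 9 members SCM (SUB, AT1G11130), a receptor kinase, fell from 17.8 ± 1.99 to 2.18 ± 1.34 RPKM, the 1 member also called adjusted over the list alone.

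Wall genes split. Of 18 expansins tested 9 rose, 4 fell and 5 did not pass, against 10 and 4 adjusted over the list alone, and the list was not called (adjusted p = 0.0684). EXPA7 (AT1G12560), an expansin of root hairs, rose from 1.2 ± 0.829 to 80.4 ± 87.6 RPKM. By contrast, EXPA4 (AT2G39700) fell from 81.2 ± 25.7 to 7.96 ± 3.82 RPKM. EXPA6 (AT2G28950) went from 11.8 ± 2.32 to 3.01 ± 0.819 RPKM. Of 15 XTH genes, which remodel xyloglucan, 11 rose, 1 fell and 3 did not pass, against 12 and 1 adjusted over the list alone (adjusted p = 0.00262, adjusted p = 0.472 with an estimated correlation). XTH17 (AT1G65310) rose by 5.87 ± 0.72 on the log2 scale and XTH18 (AT4G30280) by 5.43 ± 0.63, while XTH9 (AT4G03210) fell from 84.6 ± 9.82 to 21.1 ± 4.72 RPKM. All 8 tested genes of primary wall cellulose synthesis rose, 8 adjusted over the list alone (adjusted p = 0.000183, adjusted p = 0.472 with an estimated correlation), among them the synthase CESA6 (AT5G64740) from 41.1 ± 6.7 to 162 ± 21.3 RPKM. The endoglucanase KOR1 (GH9A1, AT5G49720) went from 68.7 ± 15.1 to 268 ± 74.3 RPKM.

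Of 19 aquaporins 18 rose and 1 fell, the same counts adjusted over the list alone (adjusted p = 1.14e-06, adjusted p = 0.472 with an estimated correlation). The median log2 change was 4.52. TIP1;2 (TIP2 in the reference, AT3G26520) rose from 47.6 ± 40.3 to 1652 ± 1041 RPKM. PIP2;8 (AT2G16850) fell from 40.4 ± 8.58 to 5.29 ± 2.45 RPKM. Of 4 vacuolar proton pump genes 3 rose, 3 adjusted over the list alone (adjusted p = 0.0408, adjusted p = 0.472 with an estimated correlation), VHA-a3 (AT4G39080) from 58.3 ± 12.7 to 203 ± 58 RPKM. DET3 (AT1G12840) went from 98.3 ± 17.4 to 270 ± 51.6 RPKM. The pyrophosphatase AVP1 had a log2 change of -0.11 and was not called.

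Several lists of maturing tissues were higher in the EZ than in the MZ. In root hair growth 20 of 24 genes rose and 4 did not pass, with 21 higher adjusted over the list alone (adjusted p = 3.66e-07, adjusted p = 0.472 with an estimated correlation). RBOHC (RHD2, AT5G51060), the oxidase of hair tips, went from 1.3 ± 1.61 to 44.6 ± 10.9 RPKM. In xylem and secondary wall 12 of 18 rose and 6 did not pass, 12 adjusted over the list alone (adjusted p = 0.00161, adjusted p = 0.519 with an estimated correlation), with the xylem peptidases XCP2 (AT1G20850) at 46.6 ± 44.1 RPKM in EZ against 1.26 ± 0.987 in MZ and XCP1 (AT4G35350) at 51.2 ± 51 against 1.6 ± 1.47. In monolignol synthesis 12 of 14 rose and 2 did not pass, against 13 higher and 1 lower adjusted over the list alone (adjusted p = 0.00161, adjusted p = 0.519 with an estimated correlation). PAL1 (AT2G37040), which opens the pathway, rose by 4.52 ± 0.88 on the log2 scale and CCoAOMT1 (AT4G34050) by 3.38 ± 0.64. In endodermis and suberin 6 of 19 rose and 13 did not pass, 4 adjusted over the list alone (adjusted p = 0.0413, adjusted p = 0.572 with an estimated correlation), a list call that quantile normalization ended (adjusted p = 0.0664). The 6 included CASP5 (AT5G15290) and CASP1 (AT2G36100), membrane proteins of the Casparian strip, with log2 changes of 3.98 ± 1.04 and 2.80 ± 1.05. EZ replicate 3 stood apart in CASP1, at 296 RPKM against 17.4 and 18.2 in the other EZ libraries, and in PAL1, at 515 RPKM against 95.7 and 76.4. The other members of these lists were not compared by library. The call of CASP1 was lost without MZ replicate 1 (adjusted p = 0.141), MZ replicate 2 (0.131), EZ replicate 3 (0.0808), DZ replicate 1 (0.0579), DZ replicate 2 (0.0619) or DZ replicate 3 (0.0554), and with no filter on low values (0.0724).

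Of 18 nutrient transport genes 8 rose and 10 did not pass, 8 adjusted over the list alone (adjusted p = 0.00888, adjusted p = 0.519 with an estimated correlation), with the sulfate transporter SULTR1;2 (AT1G78000) going from 2.97 ± 0.631 to 32.6 ± 8.9 RPKM and the phosphate transporter PHT1;1 (AT5G43350) from 0.404 ± 0.369 to 13.9 ± 12.3 RPKM. The auxin list was not called (adjusted p = 0.186), with 8 genes higher, 3 lower and 10 not passing, 8 and 3 adjusted over the list alone. Its members went both ways: the influx carrier LAX3 (AT1G77690) rose from 18.3 ± 13.9 to 159 ± 43.4 RPKM. IAA17 (AXR3, AT1G04250) went from 31.6 ± 8.04 to 324 ± 182 RPKM. By contrast, LAX2 (AT2G21050) fell from 54.1 ± 9.05 to 5.13 ± 2.73 RPKM. Of 9 cytokinin genes 5 rose, 5 adjusted over the list alone, and 4 did not pass (adjusted p = 0.012, adjusted p = 0.472 with an estimated correlation), among them the receptors AHK3 (HK3, AT1G27320) by 1.79 ± 0.31 and AHK4 (WOL, AT2G01830) by 1.27 ± 0.18 on the log2 scale.

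Phloem genes were not called as a list (adjusted p = 0.272). Of 5 members APL (AT1G79430), a regulator of phloem identity, rose from 2.81 ± 0.522 to 7.27 ± 1.91 RPKM. In limma 0 were called adjusted over the list alone, with 2 at an unadjusted p under 0.05. The call of APL was lost without MZ replicate 1 (adjusted p = 0.0547), MZ replicate 2 (0.0835), MZ replicate 3 (0.0513) or EZ replicate 1 (0.0762). Photosynthesis was not called (adjusted p = 0.272). Of 12 genes LHCA4 (AT3G47470) fell from 23.3 ± 7.95 to 8.67 ± 4.27 RPKM, the 1 also called adjusted over the list alone, and lost its call without MZ replicate 1 (adjusted p = 0.0551) or, with a log2 change of -0.95, without EZ replicate 2. Of 9 wounding and touch genes 5 rose, 5 adjusted over the list alone, and 4 did not pass (adjusted p = 0.0125, adjusted p = 0.472 with an estimated correlation). ZAT12 (RHL41, AT5G59820) went from 1.91 ± 0.701 to 17.7 ± 12.3 RPKM and TCH3 (AT2G41100) rose by 2.65 ± 0.89 on the log2 scale, a call lost without EZ replicate 1 (adjusted p = 0.0915) or EZ replicate 3 (0.0645), and without the 3 libraries numbered 3 (0.0746).

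The 5 largest rises of the EZ held the lipid-transfer type genes AT5G46900 (log2 change 6.50 ± 0.92), AT5G46890 (6.42 ± 0.85) and AT4G12510 (6.29 ± 0.91), the peroxidase gene AT3G01190 (6.26 ± 0.83) and AT2G47540 (6.09 ± 0.44) of the Ole e 1 and extensin family. The 5 largest falls were small nucleolar RNA genes listed at 0 in every EZ library, AT2G17295, AT2G43137, AT2G43139, AT3G01316 and AT3G13525. In the 3 MZ libraries AT2G17295 was at 700, 147 and 114 RPKM and AT2G43139 at 105, 154 and 79.9 RPKM. AT2G43137 and AT2G43139 overlap AT2G43110. Short genes such as these reach a high RPKM with few reads. On the line from MZ to DZ, where 0 is the mean MZ and 1 the mean DZ, EZ replicates 1, 2 and 3 lay at 0.365, 0.371 and 0.7, and without the 3 libraries numbered 3, an alternative chosen after seeing the data, 3317 genes rose and 3192 fell.

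**Figure D1:**
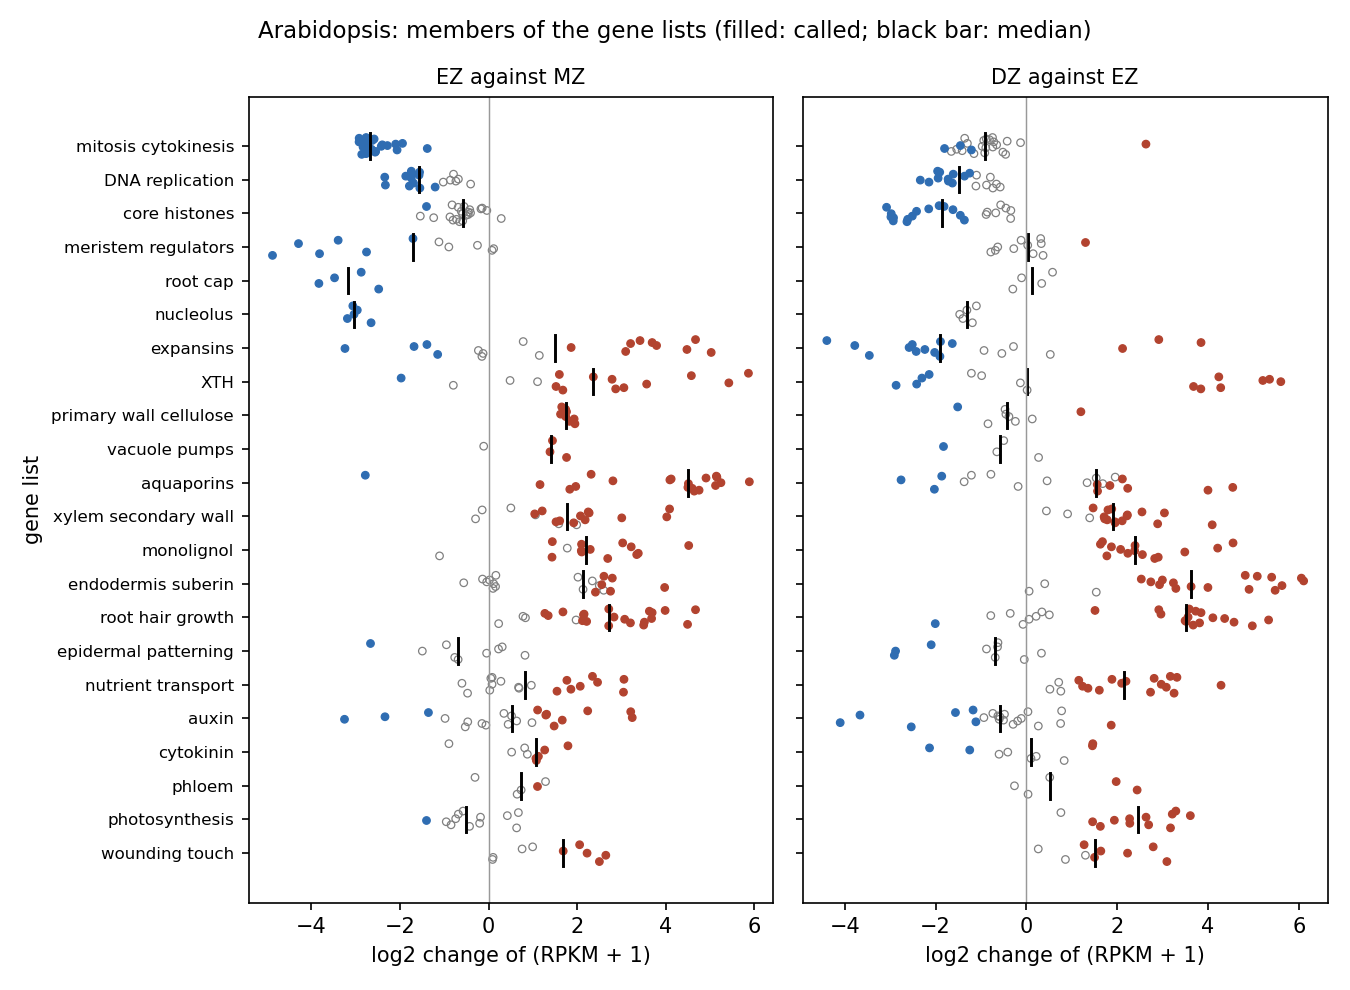
Log2 change of (RPKM + 1) for each tested member of the 22 Arabidopsis gene lists, EZ against MZ on the left and DZ against EZ on the right. Each circle is a gene, filled where called (red higher, blue lower), and each black bar is the median of a list, with the 24 mitosis genes below 0 on the left and the median of the aquaporins at 4.52.

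Between the EZ and the DZ of Arabidopsis, 7 of 22 gene lists were called higher, among them endodermis and suberin (16 of 19 genes rose), monolignol synthesis (14 of 14), nutrient transport (15 of 18) and photosynthesis (11 of 12). The 3 lower lists were core histones (15 of 22 genes fell), DNA replication (11 of 18) and expansins (11 of 18, while 3 rose). With an estimated correlation 0 of these lists were called by camera in limma, with adjusted p = 0.603 or more with an estimated correlation. CASP1 (AT2G36100) rose from 110 ± 160 RPKM in EZ to 3313 ± 1365 in DZ (SD, n = 3), a log2 change of 6.05 ± 1.05 (adjusted p = 0.00175). The expansin EXPA11 (AT1G20190) fell from 311 ± 78.2 to 15.6 ± 8.77 RPKM, a log2 change of -4.40 ± 0.67 (adjusted p = 0.000939). In all, 3857 genes rose and 3213 fell. These counts were 3314 and 3468 without the 3 libraries numbered 3 and 3697 and 3790 with quantile normalization. Which of them was larger turned in these 2 and in 2 more of 15 alternatives, without EZ replicate 3 (4397 and 4409) or DZ replicate 1 (3310 and 4053). Without DZ replicate 1, genes reaching 1 RPKM only in the DZ were not tested, which takes away higher calls. That filter does not account for the turn, since the lower calls went from 3213 to 4053. Without DZ replicate 2 (3073 higher and 2853 lower) or DZ replicate 3 (3068 and 2441), under the same filter, the larger number did not turn.

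In endodermis and suberin 16 of 19 genes rose and 3 did not pass, 16 adjusted over the list alone (adjusted p = 2.22e-07, adjusted p = 0.603 with an estimated correlation), with CASP2 (AT3G11550) going from 44.9 ± 64 to 1550 ± 666 RPKM. All 14 monolignol genes rose, 14 adjusted over the list alone (adjusted p = 9.68e-05, adjusted p = 0.603 with an estimated correlation). The ligase gene 4CL1 (AT1G51680) went from 43.6 ± 60.8 to 504 ± 59.3 RPKM. PAL4 (AT3G10340) went from 7.78 ± 10.6 to 96.7 ± 13 RPKM. In xylem and secondary wall 15 of 18 rose and 3 did not pass, with 16 adjusted over the list alone (adjusted p = 9.68e-05, adjusted p = 0.603 with an estimated correlation), among them IRX15L (IRX15-L, AT5G67210), of xylan synthesis, by 4.09 ± 0.86 and the laccase LAC4 (IRX12, AT2G38080) by 3.04 ± 0.62 on the log2 scale. The spread of CASP1 within the EZ came with EZ replicate 3, where it was at 296 RPKM against 17.4 and 18.2 RPKM in EZ replicates 1 and 2.

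In root hair growth 16 of 24 genes rose, 1 fell and 7 did not pass, the same counts adjusted over the list alone (adjusted p = 0.000202, adjusted p = 0.603 with an estimated correlation). RHS13 (AT4G02270) rose from 53.9 ± 72.9 to 1135 ± 283 RPKM. RHS19 (AT5G67400) went from 37.4 ± 48.9 to 680 ± 208 RPKM. By contrast, RSL1 (AT5G37800), a transcription factor that starts hair formation, fell from 6.35 ± 4.58 to 0.649 ± 0.411 RPKM. Epidermal patterning did not pass as a list (adjusted p = 0.0692), with 3 of 9 genes lower, 3 adjusted over the list alone. MYB23 (AT5G40330) fell from 13.4 ± 2.48 to 0.909 ± 0.257 RPKM. WER (MYB66, AT5G14750) went from 57 ± 12.6 to 12.2 ± 16.2 RPKM. Of 18 nutrient transport genes 15 rose and 3 did not pass, 15 adjusted over the list alone (adjusted p = 6.37e-07, adjusted p = 0.603 with an estimated correlation). The phosphate exporter PHO1 (AT3G23430) went from 1.32 ± 0.684 to 47.5 ± 26.8 RPKM and the nitrate transporter NRT1.5 (AT1G32450) from 0.326 ± 0.247 to 24.4 ± 32.7 RPKM, both genes of loading into the xylem.

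Of 18 expansins 11 fell, 3 rose and 4 did not pass, the same counts adjusted over the list alone (adjusted p = 0.0138, adjusted p = 0.603 with an estimated correlation). EXPB1 (AT2G20750) fell from 137 ± 7.76 to 9.77 ± 4.43 RPKM. By contrast, the root hair expansins EXPA18 (AT1G62980) and EXPA7 (AT1G12560) rose, EXPA18 from 51.9 ± 60.6 to 490 ± 52.3 RPKM and EXPA7 from 80.4 ± 87.6 to 408 ± 67.4 RPKM. XTH genes went both ways, with 7 of 15 higher, 4 lower and 4 not passing, the same counts adjusted over the list alone, and the list was not called (adjusted p = 0.288). XTH24 (AT4G30270) rose from 2.07 ± 2.18 to 128 ± 28.7 RPKM. XTH14 (AT4G25820) went from 47.9 ± 61.3 to 1165 ± 298 RPKM. By contrast, XTH5 (AT5G13870) fell from 32.9 ± 17.3 to 4.54 ± 4.91 RPKM. XTH19 (AT4G30290) went from 299 ± 50.6 to 60.3 ± 28.5 RPKM. Cellulose synthesis was not called (adjusted p = 0.277), with 1 of 8 genes higher, 1 lower and 6 not passing, 1 and 1 adjusted over the list alone. CSI1 (AT2G22125), which ties synthase complexes to microtubules, fell from 58.2 ± 11.4 to 19.8 ± 4.49 RPKM. The synthase CESA2 (AT4G39350) rose from 54.9 ± 36.2 to 114 ± 28.1 RPKM. It lost its call without EZ replicate 1 (adjusted p = 0.106), EZ replicate 2 (0.103), DZ replicate 2 (0.0843) or DZ replicate 3 (0.101).

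Aquaporins were not called as a list (adjusted p = 0.288): 7 of 19 rose, 3 fell and 9 did not pass, against 9 and 3 adjusted over the list alone. TIP2;2 (AT4G17340) rose from 316 ± 355 to 4854 ± 982 RPKM and TIP2;3 (AT5G47450) from 267 ± 283 to 3038 ± 744 RPKM. By contrast, PIP2;6 (PIP2E, AT2G39010) fell from 39.1 ± 34 to 3.92 ± 1.72 RPKM and PIP2;7 (PIP3, AT4G35100) from 1676 ± 847 to 386 ± 81 RPKM. Vacuolar proton pumps were not called (adjusted p = 0.208), and of 4 genes AVP1 (AT1G15690) fell from 366 ± 92.8 to 101 ± 17 RPKM, the 1 also called adjusted over the list alone.

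Core histones fell in the DZ, 15 of 22 with 7 not passing, 15 adjusted over the list alone (adjusted p = 2.08e-06, adjusted p = 0.603 with an estimated correlation). The H3 histone genes AT1G09200 and AT5G10400 went from 326 ± 122 to 43.7 ± 31.1 RPKM and from 193 ± 65.3 to 30.8 ± 29.3 RPKM. In DNA replication 11 of 18 fell and 7 did not pass, 12 adjusted over the list alone (adjusted p = 0.000738, adjusted p = 0.678 with an estimated correlation). The licensing factor CDT1A (AT2G31270) fell from 15.7 ± 7.52 to 2.46 ± 2.11 RPKM and TSO2 (AT3G27060), of nucleotide reduction, from 80 ± 41.2 to 18.8 ± 12.8 RPKM, a call lost without EZ replicate 1 (adjusted p = 0.0679) or EZ replicate 2 (0.0712). Mitosis and cytokinesis was not called (adjusted p = 0.0597), with 3 of 24 lower, 1 higher and 20 not passing, against 1 and 1 adjusted over the list alone. The replicate block (adjusted p = 0.0169) and quantile normalization (0.0424) put it past the threshold as lower. CDKB1;1 (AT3G54180) fell from 16.5 ± 6.19 to 4.19 ± 2.22 RPKM. AUR2 (AT2G25880), a kinase of dividing cells, rose from 8.22 ± 3.06 to 59.1 ± 28.6 RPKM.

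Meristem regulators were not called (adjusted p = 0.828), with a median log2 change of 0.03, a mean of -0.00 and a test pointing lower. Of 11 members WOX5 (AT3G11260), of the stem cell organizer, rose from 1.36 ± 0.557 to 5.17 ± 3.24 RPKM. In limma 0 were called adjusted over the list alone, with 2 at an unadjusted p under 0.05. The call of WOX5 was lost without MZ replicate 2 (adjusted p = 0.0552), EZ replicate 1 (0.0748), EZ replicate 2 (0.0614), EZ replicate 3 (0.0812) or DZ replicate 2 (0.131) and with no filter on low values (0.0541). In limma, 0 of 4 root cap and 0 of 5 nucleolar genes were called, also adjusted over the list alone, with 0 of either at an unadjusted p under 0.05. Neither list was called (adjusted p = 0.828 and 0.273). With quantile normalization the median log2 change turned from 0.11 to -0.03 for the root cap, from 0.03 to -0.00 for meristem regulators and from 0.01 to -0.03 for XTH genes. The auxin list was not called (adjusted p = 0.086), with 6 of 21 lower, 1 higher and 14 not passing, 6 and 1 adjusted over the list alone. The receptor AFB1 (GRH1, AT4G03190) fell from 149 ± 38.7 to 10.2 ± 8.02 RPKM. The auxin synthesis gene TAA1 (AT1G70560) went from 45.9 ± 12 to 2.99 ± 1.89 RPKM. Cytokinin was not called (adjusted p = 0.77), with 2 of 9 higher and 2 lower, also adjusted over the list alone. Its median log2 change was 0.10, its mean -0.04 and its test pointed lower. AHK3 (HK3, AT1G27320) rose by 1.45 ± 0.31 and AHK4 (WOL, AT2G01830) fell by 1.25 on the log2 scale, which became -0.98, under the fold minimum, without the 3 libraries numbered 3.

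Phloem was not called (adjusted p = 0.273), with 2 of 5 higher, 2 adjusted over the list alone: SEOR1 (AT3G01680), a protein of sieve elements, rose from 0.908 ± 0.706 to 9.76 ± 4.78 RPKM. SUC2 (AT1G22710), which loads sucrose, rose by 1.98 ± 0.59 on the log2 scale but lost its call without EZ replicate 1 (adjusted p = 0.07), EZ replicate 2 (0.0722) or DZ replicate 2 (0.0689). In photosynthesis 11 of 12 genes rose, 11 adjusted over the list alone (adjusted p = 4.24e-05, adjusted p = 0.603 with an estimated correlation), such as PSAF (AT1G31330) from 4.01 ± 3.85 to 51.6 ± 14.7 RPKM. PSBP1 (PSBP-1, AT1G06680) went from 3.06 ± 2.99 to 33 ± 6.16 RPKM. Of 9 wounding and touch genes 6 rose, 6 adjusted over the list alone, and 3 did not pass (adjusted p = 0.00259, adjusted p = 0.603 with an estimated correlation), with ZAT12 (RHL41, AT5G59820) going from 17.7 ± 12.3 to 138 ± 13 RPKM. ZAT10 (STZ, AT1G27730) went from 7.14 ± 4.03 to 49.7 ± 8.31 RPKM.

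The 5 largest rises of the DZ held the lipid-transfer type gene AT1G48750, listed at 0 in all MZ libraries, at 16.6 ± 28.7 RPKM in EZ and at 493, 807 and 390 RPKM in the DZ libraries, the dirigent-type gene AT3G55230 (log2 change 7.13 ± 1.03), the galactosidase BGAL4 (AT5G56870, 6.95 ± 0.56), the oxygenase DOX1 (AT3G01420, 6.91 ± 0.28) and the metallothionein MT1C (AT1G07610, 6.70 ± 0.71). The 5 largest falls held the small nucleolar RNA genes AT5G13225, AT2G20723 and AT5G58595, the precursor MIR166b (AT3G61897) and AGP30 (AT2G33790), an arabinogalactan protein that went from 844 ± 601 to 27.8 ± 20.3 RPKM. AT5G13225 was listed at 0 in every DZ library. The calls of AT2G20723 and AT5G58595 were lost without the 3 libraries numbered 3 (adjusted p = 0.0526 and 0.0652). CDKB1;2 (AT2G38620) fell by 1.46 on the log2 scale, a call lost without MZ replicate 3 (adjusted p = 0.0501), EZ replicate 1 (0.112), EZ replicate 2 (0.108), DZ replicate 2 (0.101) or DZ replicate 3 (0.113).

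Over the EDZ of Arabidopsis, the pool of the EZ and DZ libraries, 5419 genes rose and 4872 fell against MZ of 19147 tested. With quantile normalization 4602 rose and 5819 fell, and falls were also more numerous without EDZ replicate 1 (3795 and 5307), 2 (3737 and 4971) or 3 (3543 and 4130). With an EDZ column left out, genes reaching 1 RPKM only in the EDZ missed the filter of 3 columns and were not tested. The turns without a column therefore decide nothing about single libraries. The largest rises were AT1G48750, TIP2;2 (AT4G17340), CASP1 (AT2G36100), AT3G55230 and TIP2;3 (AT5G47450), with TIP2;2 going from 8.98 ± 5.67 to 2495 ± 607 RPKM (SD, n = 3). RGF3 (AT2G04025), a meristem growth peptide gene, fell from 210 ± 57 to 4.79 ± 6.92 RPKM. AT1G50060 fell by 5.68 on the log2 scale, a call lost without EDZ replicate 3 (adjusted p = 0.0567). The other 3 of the 5 largest falls were the small nucleolar RNA genes AT2G43139 and AT3G01316, both listed at 0 in the EDZ, and AT2G17295, whose call was also lost without EDZ replicate 3 (adjusted p = 0.0515).

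The lists that fell in the EDZ were mitosis (23 of 24 genes), DNA replication (17 of 18), core histones (15 of 22), meristem regulators (7 of 11), root cap (4 of 4) and nucleolus (5 of 5), with camera adjusted p of 8.58e-07, 3.39e-05, 8.69e-05, 0.00799, 0.0286 and 0.0125. Those that rose were XTH (12 of 15, with 2 lower), cellulose synthesis (8 of 8), aquaporins (17 of 19, with 1 lower), xylem (17 of 18), monolignols (13 of 14), endodermis and suberin (18 of 19), root hair growth (22 of 24), nutrient transport (16 of 17), cytokinin (4 of 9), photosynthesis (8 of 12) and wounding (7 of 9), with adjusted p of 0.000397, 0.00344, 4.74e-05, 8.58e-07, 1.43e-05, 8.58e-07, 6.76e-09, 1.98e-05, 0.036, 0.0275 and 0.0024. Every one of these 17 calls was lost with an estimated correlation, each with adjusted p = 0.389 with an estimated correlation, and the counts adjusted over the list alone were the same for all of them. Expansins (9 higher and 3 lower of 18), vacuolar pumps (3 higher of 4), epidermal patterning (4 lower of 9), auxin (7 higher and 5 lower of 21) and phloem (3 higher of 4) were not called, with adjusted p of 0.336, 0.248, 0.0957, 0.423 and 0.134 and the same counts adjusted over the list alone. The cytokinin list lost its call with quantile normalization (adjusted p = 0.0532). Among the examples, ZAT12 (RHL41, AT5G59820) rose from 1.91 ± 0.701 to 75.6 ± 6.56 RPKM and WRKY33 (AT2G38470) from 5.64 ± 2.32 to 83.3 ± 13 RPKM. PRP3 (AT3G62680), a root hair wall protein, rose from 2.7 ± 0.761 to 503 ± 138 RPKM. CDC20.2 (AT4G33260), of mitotic exit, fell from 58.7 ± 1.72 to 5.99 ± 4.59 RPKM.

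In the other species the same steps along the root were compared, with genes known only by their IDs. Tomato had the most changed genes between MZ and EZ, 3952 higher and 4503 lower, followed by maize with 3061 and 3249, soybean with 2903 and 2510, cucumber with 2575 and 1855, and rice with 1103 and 1446. As a share of the genes tested the order was tomato with 42.5%, cucumber 26.5%, maize 24.5%, soybean 16.3% and rice 12.7%. With no fold minimum cucumber had 11049 called genes and soybean 8613, so the order below tomato is not fixed. Between EZ and DZ maize had 4304 higher and 4392 lower, tomato 3537 and 2298, cucumber 2377 and 932, and rice 2069 and 1722. With quantile normalization the larger number turned to lower genes from MZ to EZ in soybean (2372 and 2959) and cucumber (2158 and 2179). Over all alternatives the larger direction from MZ to EZ turned in 0 of 14 in tomato, 3 of 15 in maize, 3 of 17 in soybean, 2 of 15 in cucumber and 1 of 16 in rice. From EZ to DZ it turned in 4 of 15 in maize, 0 of 14 in tomato, 0 of 15 in cucumber and 3 of 16 in rice. Whether species differ in these counts was not tested.

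**Figure D2:**
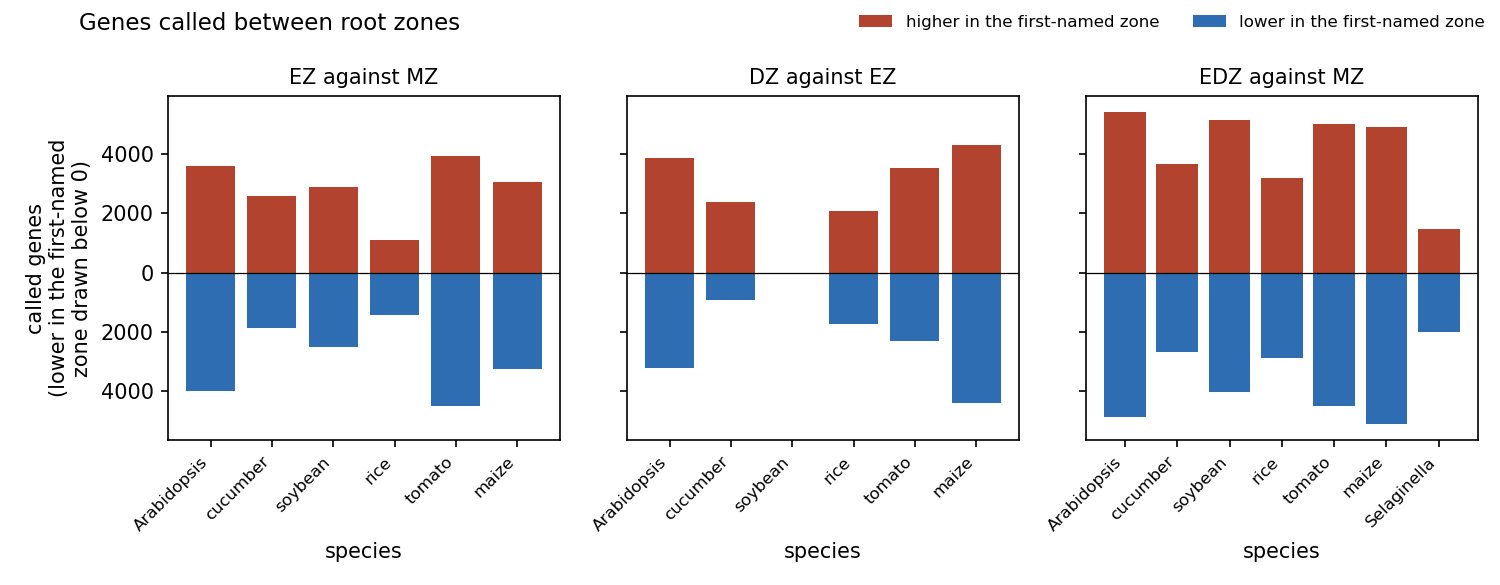
Number of genes called in each species for EZ against MZ, DZ against EZ and EDZ against MZ, with genes higher in the first-named zone above 0 and genes lower in it below 0. Soybean has 1 called gene in DZ against EZ, and Selaginella has 1478 higher and 2009 lower genes in EDZ against MZ.

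In cucumber Cucsa.301970 rose from 16.8 ± 12.9 RPKM in MZ to 4528 ± 1773 in EZ (SD, n = 3), a log2 change of 8.41 ± 0.70 (adjusted p = 3.21e-05), and Cucsa.397290 fell from 45.3 ± 5.16 to 0.0979 ± 0.17 RPKM. From EZ to DZ Cucsa.356590 rose from 2.69 ± 1.68 to 542 ± 140 RPKM and Cucsa.157120 fell from 78.7 ± 15.2 to 1.92 ± 1.67 RPKM. In tomato Solyc12g098770.1 rose from 3.01 ± 5.21 in MZ to 7339 ± 3474 RPKM in EZ, a log2 change of 11.64 ± 0.79 (adjusted p = 6.77e-06), and Solyc01g106640.2 fell from 1928 ± 1106 to 4.48 ± 3.57 RPKM. From EZ to DZ Solyc04g014350.1 rose from 1.26 ± 2.18 to 295 ± 284 RPKM and Solyc07g008420.2 fell from 315 ± 97.5 to 2.94 ± 1.02 RPKM. In maize GRMZM2G502562 rose from 18.2 ± 31.5 RPKM in MZ to 2063 ± 653 in EZ, a log2 change of 9.03 ± 1.36 (adjusted p = 0.00118), and GRMZM2G053493 fell from 382 ± 215 to 2.1 ± 2.28 RPKM. The MZ mean of GRMZM2G502562 rests on MZ replicate 3, at 54.5 RPKM against 2.06e-56 and 0.0129 RPKM in MZ replicates 1 and 2. From EZ to DZ of maize, GRMZM2G556376 was listed at 0 in the EZ and at 142, 103 and 97.9 RPKM in the DZ libraries, and GRMZM2G545347 was at 213, 237 and 293 RPKM in the EZ and listed at 0 in the DZ.

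In rice LOC_Os12g16660 rose from 0.898 ± 1.55 RPKM in MZ to 56 ± 21.5 in EZ (SD, n = 3), a log2 change of 5.14 ± 0.84 (adjusted p = 0.00939), and LOC_Os04g44130 fell from 273 ± 62.7 to 15.9 ± 20.9 RPKM. From EZ to DZ LOC_Os08g24200 rose from 54.9 ± 91.1 to 2014 ± 2501 RPKM (adjusted p = 0.0259). Its call was lost without EZ replicate 2 (adjusted p = 0.0886), EZ replicate 3 (0.0871), DZ replicate 1 (0.0566) or DZ replicate 2 (0.0563) and with a pseudocount of 0.1 (0.0523). In the same step LOC_Os10g31530 fell from 58.3 ± 25.4 to 4.13 ± 4.36 RPKM. The 2549 called genes of EZ against MZ became 0 in limma without MZ replicate 2 (5441 genes at an unadjusted p under 0.05) or without MZ replicate 3 (5570), 1375 without EZ replicate 1 and 1326 (487 higher and 839 lower) with the block on description numbers. The calls of both genes named for that step were lost without MZ replicate 2 (adjusted p = 0.0607 for LOC_Os12g16660 and 0.0871 for LOC_Os04g44130) or MZ replicate 3 (0.0509 and 0.08), and that of LOC_Os04g44130 also without EZ replicate 2 (0.0558) or EZ replicate 3 (0.0511) and with a block on description numbers (0.066). The 3791 called genes of DZ against EZ became 2237 without EZ replicate 2 and 2094 without EZ replicate 3. MZ replicate 1 and EZ replicate 1 of rice lay nearer to the DZ than the others of their zones, at 0.204 and 0.637 on the line from MZ to DZ, and without the 3 libraries numbered 1, an alternative chosen after seeing the data, 3749 and 4818 genes were called in the steps from MZ to EZ and from EZ to DZ.

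In soybean GLYMA17G14921 rose from 2.81 ± 2.35 RPKM in MZ to 830 ± 462 in EZ (SD, n = 3), a log2 change of 7.80 ± 0.59 (adjusted p = 0.00227), and GLYMA08G43240 fell from 180 ± 149 to 2.41 ± 2.31 RPKM. Between EZ and DZ only GLYMA16G21150 was called by limma, from 0, 0.0539 and 0 RPKM in the EZ libraries to 3.32, 3.08 and 4.14 in the DZ libraries, with 5085 genes at an unadjusted p under 0.05. It was outside the rule for named genes and was named after its values were seen. Its call was lost with a pseudocount of 0.1 (adjusted p = 0.35), quantile normalization (0.0982), the replicate block (0.0778), a block on description numbers (0.302), and without MZ replicate 1 (0.175), MZ replicate 2 (0.222), MZ replicate 3 (0.236), EZ replicate 1 (0.13) or EZ replicate 3 (0.166). For DZ against EZ, 119 genes were called without EZ replicate 2 and 2 with no filter on low values. The replicate block called 0 in limma, with 9950 at an unadjusted p under 0.05. Limma also called 0 without MZ replicate 1 (4344 at an unadjusted p under 0.05), MZ replicate 2 (3820), MZ replicate 3 (3823), EZ replicate 3 (1839), DZ replicate 1 (2705), DZ replicate 2 (3720) or DZ replicate 3 (5499). The 5413 called genes of EZ against MZ became 1494 without MZ replicate 2, 1187 without MZ replicate 3, 2932 without EZ replicate 1 and 3007 without EZ replicate 2. On the line from MZ to DZ the MZ libraries 1, 2 and 3 of soybean lay at 0.228, -0.0179 and -0.0936, its EZ libraries at 0.763, 0.865 and 0.363 and its DZ libraries at 0.992, 0.877 and 0.876. In alternatives chosen after seeing the data, 1165 genes were called from MZ to EZ without the 3 libraries numbered 1, and limma called 0 without the 3 numbered 2 (6886 at an unadjusted p under 0.05). The calls of GLYMA17G14921 and GLYMA08G43240 were also lost without the 3 numbered 2 (adjusted p = 0.102 and 0.134).

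**Figure D3:**
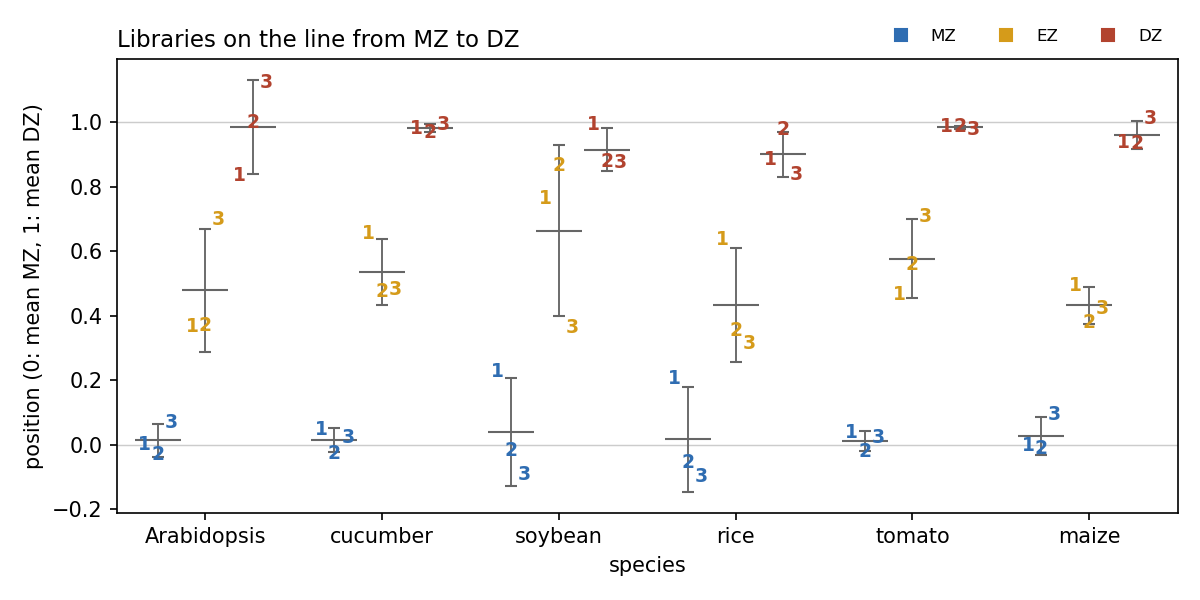
Position of each library of 6 species on the line from the mean MZ (0) to the mean DZ (1) of its species in log2(RPKM + 1), computed over the tested genes with the library itself left out of the means, where digits are replicate numbers, horizontal bars means and vertical bars SD (n = 3). EZ replicates 2 and 3 of soybean lie at 0.865 and 0.363, and EZ replicate 3 of Arabidopsis lies at 0.7.

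Selaginella, a lycophyte, had 1478 genes higher and 2009 lower in its EDZ than in its MZ, of 12650 tested. These were 1671 and 1634 with quantile normalization, so the excess of lower genes depended on the scaling. They were 1535 and 1488 without MZ replicate 1 and 1512 and 1444 without MZ replicate 3. With an MZ library left out, genes reaching 1 RPKM only in the MZ missed the filter of 3 libraries and were not tested. That takes away lower calls whichever library goes, so these turns decide nothing about single libraries. The largest rises were selmo_404277, from 10.3 ± 2.54 to 2847 ± 1057 RPKM (SD, n = 3), a log2 change of 7.93 ± 0.31 (adjusted p = 5.43e-06), and selmo_117229, from 1.84 ± 0.97 to 606 ± 277 RPKM. The largest falls were selmo_103546, from 109 ± 3.33 to 0.381 ± 0.063 RPKM, a log2 change of -6.32 ± 0.14 (adjusted p = 1.78e-07), and selmo_413644, from 166 ± 28.5 to 4.94 ± 7.49 RPKM. In the pooled EDZ of the other species, against MZ, 3671 genes were higher and 2667 lower in cucumber, 5153 and 4027 in soybean, 3189 and 2880 in rice, 5020 and 4520 in tomato and 4905 and 5110 in maize. Quantile normalization turned the majority to lower genes in cucumber (2936 and 3756), soybean (4404 and 5080), rice (2829 and 3601) and tomato (4179 and 5736), and gave 4493 and 5698 in maize. The share of higher calls went from 57.9% to 43.9% in cucumber and from 52.6% to 42.1% in tomato. Without EDZ replicate 1, 2 or 3, lower genes were also more numerous in soybean (2747 and 3276, 2416 and 3633, 3212 and 4222), rice (2378 and 2804, 2159 and 2849, 2462 and 2893) and tomato (3434 and 4704, 3289 and 4355, 3056 and 4387). In maize the counts were then 3382 and 4881, 3489 and 5280, and 3196 and 4955, while without MZ replicate 1, 2 or 3 higher genes were more numerous (4599 and 4432, 4701 and 4193, 5267 and 4464). In cucumber they were 2606 and 2493, 2843 and 2709, and 2780 and 2806 without EDZ replicate 1, 2 or 3. Over all 11 alternatives the larger direction turned in 2 in cucumber, 5 in soybean, 7 in rice, 4 in tomato and 3 in maize. With a column left out, genes reaching 1 RPKM only in its zone missed the filter of 3 columns and were not tested. Turns away from that zone therefore decide nothing about single libraries, and the larger direction is not settled by these counts.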

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

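The tests below on soybean and Arabidopsis, those on zone boundaries and the counts over other splits of the libraries were chosen only after the results they bear on had been seen, while the test of depth in rice was written before its result was seen. Of the gene rows whose IDs name no species, which no comparison used, 1110 with clone-style names and 16 with IDs that begin with a number held at least 1 RPKM in at least 3 columns of the table of 3 zones. They stood out as signal in data outside the comparisons. For the clone-style rows the weights of DZ in the EDZ columns were 0.478, 0.49 and 0.493 for numbers 1, 2 and 3, against 0.475, 0.487 and 0.492 in maize. For the rows with IDs that begin with a number they were 0.51, 0.438 and 0.481, on only 13, 14 and 12 rows, against 0.509, 0.434 and 0.48 in rice.

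The 3 EZ libraries of soybean lay far apart on the line from MZ to DZ, at 0.763, 0.865 and 0.363, and limma called 1 gene between EZ and DZ, with 5085 at an unadjusted p under 0.05. Whether the EZ samples were cut at different places along the root cannot be told apart from a true difference in growth, since the correlation of EZ replicate 2 minus EZ replicate 3 with DZ against MZ (r = 0.739 across genes) largely restates their positions. A swap of EZ replicate 2 with a DZ library cannot be told apart either, since the lowest DZ library lay at 0.876, above EZ replicate 1 by 0.112, within the spread of 0.4. Across genes EZ replicate 2 correlated at 0.801, 0.924 and 0.969 with DZ replicates 1, 2 and 3. With EZ replicates 1 and 3 it correlated at 0.864 and 0.863. EZ replicate 1 also correlated best with a DZ library, DZ replicate 1, at 0.894. Whether the libraries numbered 1 of soybean were handled apart cannot be told apart either, since without them limma called 0 genes between EZ and DZ (1787 at an unadjusted p under 0.05) with 2 libraries left in each zone. Replicate 1 lay nearest to DZ in MZ (0.228 against -0.0179 and -0.0936) and highest in DZ (0.992) but between the others in EZ, which leaves this open, as is a single wrong label. In the labels the description numbers follow each other over the zones for soybean replicates 2 and 3 but not for replicate 1. What these numbers stand for was not examined.

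EZ replicate 3 of Arabidopsis lay nearer to DZ, at 0.7, than EZ replicates 1 and 2, at 0.365 and 0.371. Sequencing depth is argued against, since EZ replicates 1 and 2 differed in position by 0.00594 at about 7.67 and 21.1 M reads. A swap with a DZ library is argued against too, since the lowest DZ library lay at 0.833, above the other EZ libraries by 0.462 against a spread of 0.29. Whether EZ replicate 3 was cut farther from the tip cannot be told apart from a true difference between the samples, since the correlation of its difference from the others with DZ against MZ (r = 0.763 across genes) largely restates its position. A DZ library wrongly labelled as EZ replicate 3 is argued against by correlations across genes. EZ replicate 3 correlated at 0.850, 0.831 and 0.801 with DZ replicates 1, 2 and 3, which correlated with each other at 0.938 to 0.965. With EZ replicates 1 and 2 it correlated at 0.891 and 0.895, against 0.974 between them. Another wrong label stays open.

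The rice libraries numbered 1 lay nearer to DZ in both MZ and EZ, with MZ replicate 1 at 0.204 and EZ replicate 1 at 0.637. Low depth as the source is argued against, since among the 9858 genes of at least 10 RPKM on average EZ replicate 1 still lay 0.32 above the mean of the other EZ libraries, against 0.304 over all tested genes. Whether zone boundaries were placed farther from the tip in the samples numbered 1 cannot be told apart from a true difference between the samples, since the correlation of the difference of EZ replicate 1 with DZ against MZ of the libraries numbered 2 and 3 (r = 0.537 across genes) largely restates its position. The description numbers of the rice libraries numbered 1 follow each other and lie apart from those of the other rice libraries. Whether these libraries were handled apart was not tested.

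Each comparison has 10 splits of its 6 libraries into 3 and 3, which are too few for a share under 0.05, since the smallest share is 0.1. Every other split also holds libraries of both zones on each side, so a true difference between zones widens its residual spread. Low counts in the other splits were therefore to be expected and do not show how many calls arise without a difference. The real split called the most genes, so that 1 split had as many, in 18 comparisons, and 2 splits had as many in soybean DZ against EZ. For EZ against MZ the real split and the highest other called 7605 and 3 genes in Arabidopsis, 4430 and 1 in cucumber, 5413 and 1 in soybean, 2549 and 3 in rice, 8455 and 2 in tomato and 6310 and 5 in maize. For DZ against EZ these were 7070 and 351 in Arabidopsis, 3309 and 3 in cucumber, 1 and 343 in soybean, 3791 and 1 in rice, 5835 and 3 in tomato and 8696 and 8 in maize. For EDZ against MZ they were 10291 and 0 in Arabidopsis, 6338 and 1 in cucumber, 9180 and 0 in soybean, 6069 and 1 in rice, 9540 and 0 in tomato, 10015 and 2 in maize and 3487 and 0 in Selaginella. The soybean split with 343 genes set EZ replicates 1 and 3 and DZ replicate 1 against EZ replicate 2 and DZ replicates 2 and 3, and the Arabidopsis split with 351 set EZ replicates 1 and 2 and DZ replicate 1 against EZ replicate 3 and DZ replicates 2 and 3. These are the groupings that undo a swap of DZ replicate 1 with EZ replicate 2 in soybean and with EZ replicate 3 in Arabidopsis. In Arabidopsis such a swap is argued against above, so a count of this size does not decide for a swap. The soybean count of 343 against 1 points to a structure of the samples, which the splits do not identify, and the real count itself moved between 0, as in limma without MZ replicate 1 (4344 at an unadjusted p under 0.05), and 119 without EZ replicate 2. Where the numbers pair the libraries, the other splits that part every number, as the real one does, called at most 3 genes in EZ against MZ, 8 in DZ against EZ and 1 in EDZ against MZ, and the remaining splits keep a pair on the same side.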

How the results depend on the processing

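The alternatives that left out all libraries of a number were chosen only after the results had been seen, and the others were planned. For the changes below the cause was not tested, except that dropping the fold minimum adds genes by construction and leaving out libraries lowers the number of samples.

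Leaving out each library in turn gave from the lowest to the highest count 6126 to 8169 called genes for EZ against MZ, 5509 to 8806 for DZ against EZ and 7673 to 10098 for EDZ against MZ in Arabidopsis. In the same order the ranges were 3531 to 4902, 2880 to 3794 and 5099 to 6485 in cucumber, 1187 to 8075, 0 to 119 and 6023 to 9775 in soybean, 0 to 3305, 2094 to 4725 and 4836 to 6498 in rice, 7424 to 9297, 5179 to 6602 and 7443 to 9272 in tomato, and 5318 to 6611, 7547 to 8804 and 8151 to 9731 in maize. In Selaginella the range was 2798 to 3278. The counts of 0 come from limma, with 4344 soybean genes at an unadjusted p under 0.05 without MZ replicate 1 and 5441 rice genes without MZ replicate 2. Without the 3 libraries numbered 1, soybean EZ against MZ had 1165 called genes and DZ against EZ 0 in limma (1787 at an unadjusted p under 0.05). Without the 3 numbered 2, both had 0 (6886 and 3797). Arabidopsis without the 3 numbered 3 had 6509 and 6782 and rice without the 3 numbered 1 had 3749 and 4818.

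With no fold minimum, cucumber had 11049, 8745 and 12494 called genes for EZ against MZ, DZ against EZ and EDZ against MZ, rice 5031, 6338 and 10269, tomato 13786, 10301 and 14664, maize 12392, 14283 and 16133, soybean 8613 and 14417 for EZ against MZ and EDZ against MZ, and Selaginella 6360. The 1 called gene of soybean DZ against EZ became 2 with no filter and 0 in limma with a pseudocount of 0.1 (4703 at an unadjusted p under 0.05), quantile normalization (5162) and the block on description numbers (5088). That block gave 1326 genes in rice EZ against MZ. The pseudocount, the filter and quantile normalization kept the other 18 of 19 counts within 1.5 times the reported ones.

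The replicate block, which pairs libraries of the same number, took soybean DZ against EZ to 0 in limma (9950 at an unadjusted p under 0.05) and the mitosis list of DZ against EZ past the threshold (adjusted p = 0.0169). It changed no other call of a list or named Arabidopsis gene, and no other count by over 1.5 times. The numbers did not pair the libraries in cucumber DZ against EZ (3346 called with the block), tomato EZ against MZ (8514) and EDZ against MZ (9561) and Selaginella (3517), where the lowest correlation was 0.02. Each library correlated best with its own number in cucumber DZ against EZ and tomato EDZ against MZ but not in the other 2.

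Among the 66 list results, quantile normalization ended the calls of endodermis and suberin in EZ against MZ (adjusted p = 0.0664) and of cytokinin in EDZ against MZ (0.0532) and made mitosis in DZ against EZ a call (0.0424). A pseudocount of 0.1 reversed the direction of the root cap list in DZ against EZ (adjusted p = 0.995), which was not called in either case. With an estimated correlation all 44 calls were lost, with adjusted p of 0.502, 0.519, 0.572 and 0.472 in EZ against MZ, 0.678 and 0.603 in DZ against EZ and 0.389 in EDZ against MZ. Of the named Arabidopsis genes 5 of 55, 8 of 56 and 2 of 58 lost their call in some alternative, and 0 reversed in limma. Depth limits genes under about 0.143 RPKM at 1 kilobase in Arabidopsis. The block on description numbers was not run for EDZ against MZ, whose columns pool libraries. Comparisons of gene families and between species were not run.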

Other observations

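The groups of Arabidopsis genes by product description in the reference table and their tests were chosen only after the data had been seen, as 183 groups tested with camera and adjusted over the groups. Between MZ and EZ, 104 of 174 pentatricopeptide repeat genes, whose products process RNA in organelles, fell (adjusted p = 2.22e-17, adjusted p = 0.705 with an estimated correlation). Among genes of mitochondrial transcription termination factors 21 of 28 fell (adjusted p = 1.04e-06, adjusted p = 0.705 with an estimated correlation). Of 18 DEAD-box RNA helicase genes 14 fell (adjusted p = 3.1e-05) and of 17 pseudouridine synthase genes 13 fell (adjusted p = 3.78e-05), each with adjusted p = 0.705 with an estimated correlation. Of 86 genes with cysteine- and histidine-rich C1 domains 54 rose and 5 fell (adjusted p = 2.03e-09), of 43 of the lipid-transfer type 26 rose and 3 fell (adjusted p = 0.000767) and of 21 for amino acid transporters 17 rose and 2 fell (adjusted p = 0.000424), each with adjusted p = 0.705 with an estimated correlation.

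Between EZ and DZ, 34 of 48 peroxidase genes rose and 6 fell (adjusted p = 6.26e-05, adjusted p = 0.874 with an estimated correlation). Of 21 genes with VQ motifs 16 rose (adjusted p = 1.58e-05), of 15 berberine-type oxidase genes 12 rose (adjusted p = 0.000253) and of 19 dirigent-type genes 13 rose (adjusted p = 0.00171), each with adjusted p = 0.874 with an estimated correlation. Of 19 galactosyltransferase genes 11 fell and 1 rose (adjusted p = 0.00116, adjusted p = 0.874 with an estimated correlation).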
